A study of Homo sapiens with 72 samples.

How the data were processed

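Nasal scrapes, in which cells are scraped from the lining of the nose, were collected in a randomized, placebo-controlled crossover trial of single corticosteroid doses in people with grass pollen allergy. Each of 19 subjects could give a baseline scrape without allergen challenge, called period 0, and a scrape in each of 3 challenge periods. The labels give the subject and the period of each array. They do not say which treatment a subject received in which period, at what time of day a scrape was taken, or whether the numbers 1 to 3 follow the order of the visits, so the periods were compared as labelled and no treatment was assigned to any sample. The series holds 72 arrays. 1 array of period 3, which the labels mark as having failed quality control, was left out, and 71 were used: 18 of period 0, 19 of period 1, 19 of period 2 and 15 of period 3.

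Per the labels' protocols, 50 ng of total RNA was amplified with a single-primer isothermal method (Ribo-SPIA, Ovation WB), and the cDNA was fragmented, labelled with biotin and hybridised to a custom Affymetrix array. Amplification from small inputs adds noise that falls mostly on dim transcripts. The authors deposited one table of log2 expression values, and the submitters' processing notes name RMA and Affymetrix Power Tools with no version. RMA subtracts background, forces the arrays to one distribution and summarises the probes of a probe set, so a shift shared by all transcripts is removed from the values and large differences of dim transcripts are understated. Values ran from 1.19 to 14.48, and array medians lay between 5.56 and 5.73. No 2 columns were identical. The precision of each difference is limited by the number of arrays. As a reference for background, 523 probe sets designed against viruses had a median of 2.87 and a 95th percentile of 4.87 over all arrays, and 13445 of the 19769 genes had a mean above that percentile.

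Of the 52377 probe sets, 35184 had 1 gene in the platform annotation, 374 had several and 16819 had none. Symbols were updated through the gene identifier for 35134 probe sets with the RefSeq gene table of GRCh38.p14. No genome build is named for the custom array, so no coordinates are given. XIST and Y-linked genes, 41 probe sets, were left out of every test. Each gene was represented by the probe set with the highest mean over all samples, which settled the choice for the 8723 genes with more than 1 probe set. No filter on dim genes was applied.

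Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the log2 values, in one fit over the 4 periods with the subject as a fixed block and 49 residual degrees of freedom. A gene was called past the threshold at a Benjamini-Hochberg adjusted p under 0.05 over all 19769 genes. The contrasts were the mean of periods 1 to 3 against period 0, each of those periods against period 0, each pair of periods 1 to 3, and a moderated F test among periods 1 to 3. The pairing comes from the subject numbers of the labels: same-numbered arrays come from 1 person. The deviations of 2 arrays from their period means had a median correlation over genes of 0.329 within subjects and -0.0179 between subjects, and the mean within-subject correlation was over 0.1 for 15 of the 19 subjects.

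Before the data were examined, 28 gene lists were fixed from textbook knowledge: allergic, glucocorticoid and innate responses and markers of the cell types a nasal scrape can hold. Of their 692 entries 618 were measured, 13 to 37 per list. Lists were tested with camera, which asks whether a list's members differ more than other genes, with a preset correlation between genes of 0.01 and again with an estimated correlation, adjusting over the 28 lists. A list score was the mean log2 value of the list's members in a sample. Within-subject differences in score were tested with a two-sided paired permutation test of 100000 sign flips. It covered the 18 subjects with period 0, or the 15 to 19 subjects with both periods where 2 single periods were compared. Intervals of mean score differences are 95% intervals from the t distribution. Genes named for the main comparison were to be the 14 largest increases and 10 largest decreases past the threshold that had their direction in at least 75% of subjects. For pairs of challenge periods they were the 5 largest in each direction past the threshold, and for each list up to 4 members with the smallest p. Alternatives covered normalization, dim genes, probe sets, the block, the variance model, array weights, cell composition, the subjects used and the failed array.

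The same steps were tested on simulated data made from the real genes' subject means and residual spreads for the mean of periods 1 to 3 against period 0. Of 200 changed genes among 19769, 50 at each size, 50% were recovered at a log2 change of 0.25, 80% at 0.5, 100% at 1 and 100% at 2. Of the 179 calls, 165 fell on these genes, 5 on the 30 interferon-stimulated genes, which were shifted by -0.4 as a list, and 9 on genes left unchanged. These shares vary with the genes drawn. The simulation draws genes independently and so leaves out the shared movements of genes in real scrapes. Plots were drawn with Matplotlib 3.10.9, pandas 2.3.3 and NumPy 2.4.6 in Python 3.11.15.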

Results

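Whole-genome expression was measured on 71 arrays of nasal scrapes from 19 subjects with grass pollen allergy. The arrays comprised 18 of period 0, taken without allergen challenge, and 19, 19 and 15 of the challenge periods 1, 2 and 3. The trial tested how single corticosteroid doses change the response to nasal allergen. The labels do not give the treatment of a period, so it is not known which arrays followed placebo and which the active drug, and no treatment effect was estimated. Values are log2 RMA values, and a difference is given as a log2 difference with its standard error.

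The first comparison asked how scrapes of the challenge periods differed from those of period 0 in the same subjects. Among the genes past the threshold, the largest differences were decreases. CIART, a repressor within the circadian clock, was 3.9-fold lower in the challenge periods (log2 difference -1.96, SE 0.19, adjusted p = 6.77e-10, limma) and was lower in 17 of 18 subjects. NR1D1, which encodes the nuclear receptor REV-ERB alpha, was 2.78-fold lower (-1.47, SE 0.16, adjusted p = 7.32e-09), and PER1, a clock gene that glucocorticoids also induce, was 2.24-fold lower (-1.16, SE 0.15, adjusted p = 9.12e-07), each in 17 of 18 subjects. These 3 were the called genes that differed by more than 2-fold. CIART averaged 9.25 ± 0.77 (SD, n = 18) in period 0, 7.08 ± 0.84 (n = 19) in period 1, 7.19 ± 0.61 (n = 19) in period 2 and 7.61 ± 0.82 (n = 15) in period 3.

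**Figure D1:**
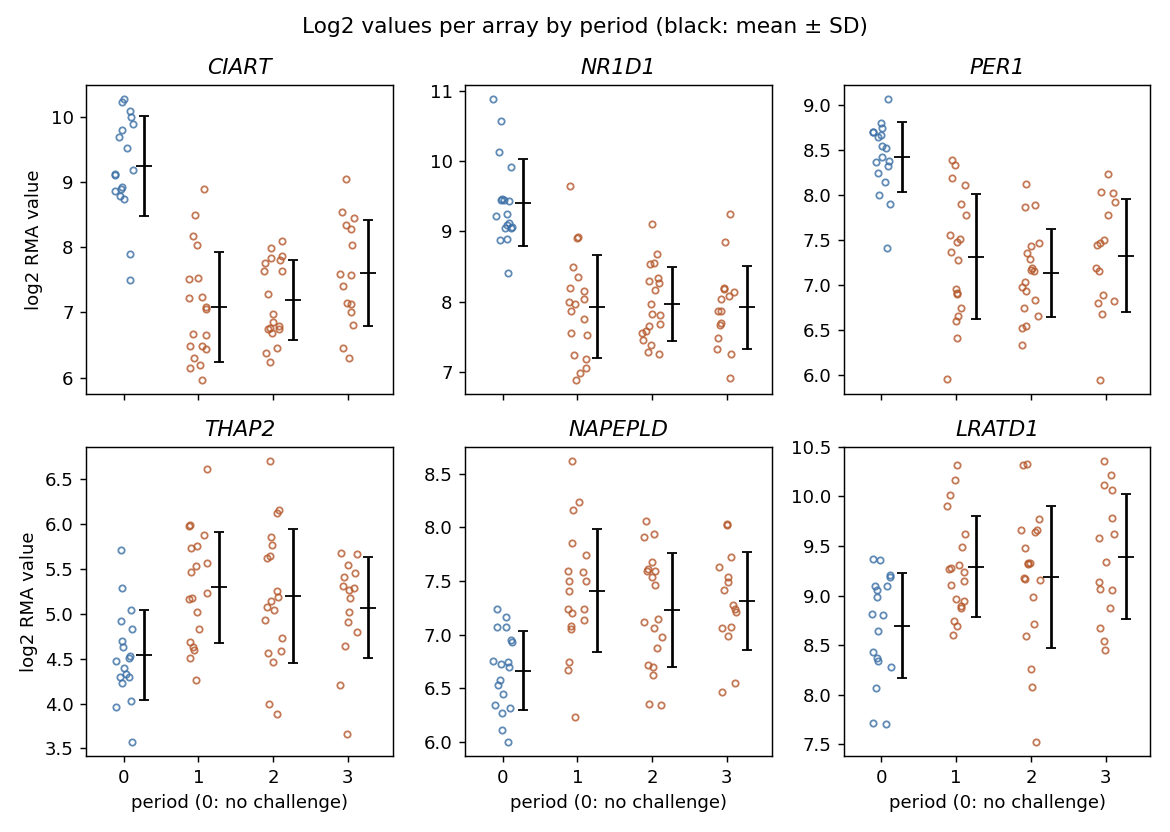
Log2 RMA values (y axes) of the 3 genes with the largest decreases and the 3 with the largest increases among those past the threshold, by period (x axes). Each circle is 1 array, blue for period 0 and orange for the challenge periods, and black bars are means ± SD. The mean of CIART was 9.25 in period 0 and between 7.08 and 7.61 in the challenge periods, and the mean of NAPEPLD was 6.67 in period 0 and between 7.23 and 7.41 in the challenge periods.

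In all, 23 of 19769 genes passed the threshold, 13 higher and 10 lower, and each met the rule for named genes. The other 7 lower genes were ST7-AS1 (-0.70, SE 0.14), TEF, a PAR bZIP transcription factor of clock output (-0.64, SE 0.11), NR1D2, the paralog of NR1D1 (-0.60, SE 0.09), KLF9, a transcription factor induced by glucocorticoids (-0.57, SE 0.099), E2F6 (-0.40, SE 0.091), the histone gene H3-3B (-0.34, SE 0.056) and DKFZP586I1420 (-0.28, SE 0.062). E2F6 was lower in 18 of 18 subjects, but its other probe set showed no such difference (-0.01, SE 0.075). All 3 probe sets of NR1D2 and both of KLF9 were lower, with log2 differences of -0.60, -0.84 and -0.78 for NR1D2 and -0.57 and -0.59 for KLF9. The dimmer second probe sets of PER1 (mean 4.28; -0.35, SE 0.14, adjusted p = 0.491) and TEF (mean 2.65; 0.04, SE 0.058, adjusted p = 0.963) did not pass. Among the 13 higher genes, THAP2 was 1.6-fold higher (0.68, SE 0.15), though its period 0 mean of 4.54 lay under the 95th percentile of virus probe sets. NAPEPLD, which makes N-acylethanolamines, was 1.58-fold higher (0.66, SE 0.11), and LRATD1 was 1.47-fold higher (0.56, SE 0.11) and higher in 18 of 18 subjects, with 0.52, 0.15 and 0.09 for its other probe sets. The mitochondrial transporter ABCB8 (0.33, SE 0.055) was likewise higher in 18 of 18 subjects, with 0.18 (SE 0.084, adjusted p = 0.623) for its other probe set. Smaller increases were those of MMACHC (0.34), an enzyme of cobalamin handling, ZNF234 (0.34), VWA8 (0.33), TBC1D24 (0.31), LINC02987 (0.28), the Polycomb gene EED (0.24), KIFBP (0.24), INTS13 of the Integrator complex (0.23) and TMEM250 (0.19). The second probe set of VWA8 did not show the increase (-0.04, SE 0.095), and that of LINC02987 had 0.17 (SE 0.067, adjusted p = 0.504). The count was 79 with array weights, 60 of 51586 with every probe set tested by itself, 9 without the subject block and 11 when 1 subject was left out, and the scores of ciliated cells, or of ciliated, neutrophil and squamous genes, as covariates gave 57 and 48.

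Of the 28 fixed lists, 11 passed camera's test with the preset correlation, 10 lower and 1 higher, and none with an estimated correlation, where the smallest adjusted p was 0.425. The estimate was 0.66 for interferon-stimulated genes, 0.63 for T and NK cell markers and 0.07 for heat shock genes, against the preset 0.01. Where the estimate is high, the adjusted p with the preset correlation overstates the evidence. All 30 interferon-stimulated genes had negative differences, with a median of -0.41 (adjusted p = 3.88e-17; adjusted p = 0.425 with an estimated correlation). No member passed the test by itself over all genes or adjusted over the list alone; CMPK2 had -0.58, GBP1 -0.69, IFIT3 -0.63 and IFIT1 -0.65. All 25 T and NK cell markers likewise had negative differences, with a median of -0.34 (adjusted p = 1.03e-09; adjusted p = 0.594 with an estimated correlation), among them CD3G with -0.43 and LCK with -0.35. The score of the interferon list differed by -0.40 ± 0.76 (SD, n = 18) and was lower in 13 of 18 subjects (permutation p = 0.0377, adjusted p = 0.271), and that of the T and NK list by -0.33 ± 0.65 (SD, n = 18; permutation p = 0.0467, adjusted p = 0.271). Monocyte, macrophage and dendritic cell markers had a median of -0.16 (adjusted p = 0.00324; adjusted p = 0.634 with an estimated correlation), and complement genes, led by C1QA (-0.41) and C1QC (-0.39), a median of -0.10 (adjusted p = 0.00769; adjusted p = 0.594 with an estimated correlation).

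Among the 32 measured glucocorticoid-induced genes, PER1 and KLF9 were lower over all genes tested and were also the only 2 past the threshold when adjusted over the list alone. The list's median was -0.03 (adjusted p = 0.0269; adjusted p = 0.594 with an estimated correlation), and the mean of the other 30 members differed by -0.03 ± 0.27 (SD, n = 18; permutation p = 0.674). In the list of mucosal antioxidant and detoxification genes the median was -0.04 (adjusted p = 0.00769; adjusted p = 0.594 with an estimated correlation). Its CYP1B1, an aryl hydrocarbon receptor target, had -1.61 (SE 0.39), lower in 16 of 18 subjects, which passed adjusted over the list alone (adjusted p = 0.00329) but not over all genes (adjusted p = 0.0829). The remaining lower lists were B and plasma cell markers with a median of -0.14, squamous differentiation genes with -0.14, cell cycle genes with -0.10 (each adjusted p = 0.0269) and NF-kB cytokines and chemokines with -0.17 (adjusted p = 0.0323); with an estimated correlation the adjusted p was 0.716 for the first and 0.779 for the other 3. The higher list was that of heat shock genes, with a median of 0.04 and 13 of 15 members positive (adjusted p = 0.00769; adjusted p = 0.425 with an estimated correlation).

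Lists tied to allergy did not pass for the mean of periods 1 to 3. These periods pool treatments that the labels do not give, so this does not tell whether allergen without the drug raised the lists. Of 37 genes of type 2 inflammation and the IL-13 response of epithelium, 22 had positive differences, and the list's median was 0.08 (adjusted p = 0.304). Against period 0, the list's median was -0.04 in period 1, 0.04 in period 2 and 0.12 in period 3. IL5 had 0.80 (SE 0.32), IL13 0.31 (SE 0.14), ITLN1 0.88 (SE 0.40) and NOS2 -0.69 (SE 0.29), none past the threshold, and the period 0 means of IL5 and IL13, 2.23 and 3.36, lay under the 95th percentile of virus probe sets. Eosinophil markers had a median of 0.02 (adjusted p = 0.325). CLC, the Charcot-Leyden crystal protein of eosinophils, had 1.77 (SE 0.54) and was higher in 17 of 18 subjects, which passed adjusted over the list alone (adjusted p = 0.0266) but not over all genes (adjusted p = 0.273). The eosinophil score differed by 0.17 ± 0.30 (SD, n = 18; permutation p = 0.0288, adjusted p = 0.271). Mast cell and basophil markers had a median of -0.04 (adjusted p = 0.54).

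The other 14 lists did not pass either. Medians were -0.12 for ciliated cells, 0.05 for neutrophils, -0.03 for secretory and goblet cells, -0.07 for submucosal glands, -0.07 for basal cells, -0.02 for olfactory epithelium, 0.01 for endothelium and fibroblasts and -0.05 for red cells and platelets. They were -0.07 for the inflammasome and IL-1 family, -0.02 for the eicosanoid pathway, 0.05 for immediate early genes, 0.01 for matrix remodelling and epithelial repair, 0.02 for tight junctions and adhesion and 0.00 for the housekeeping control list. For neutrophils the median and mean were positive while camera's direction was down, and for endothelium and fibroblasts the median was 0.01 and the mean -0.04. Single members passed when adjusted over the list alone in 3 of these lists: MARVELD2 of tight junctions had 0.24 (SE 0.06, adjusted p = 0.00446), TGFB2 of the repair list 0.68 (SE 0.20, adjusted p = 0.0377) and PRB4 of the gland list 0.96 (SE 0.31, adjusted p = 0.0443). None of the 3 passed over all genes. The mix of cells differed widely between scrapes: the first principal component held 38.7% of the variance, and the SD of the within-subject difference in score was 1.72 for ciliated and 1.66 for neutrophil markers.

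**Figure D2:**
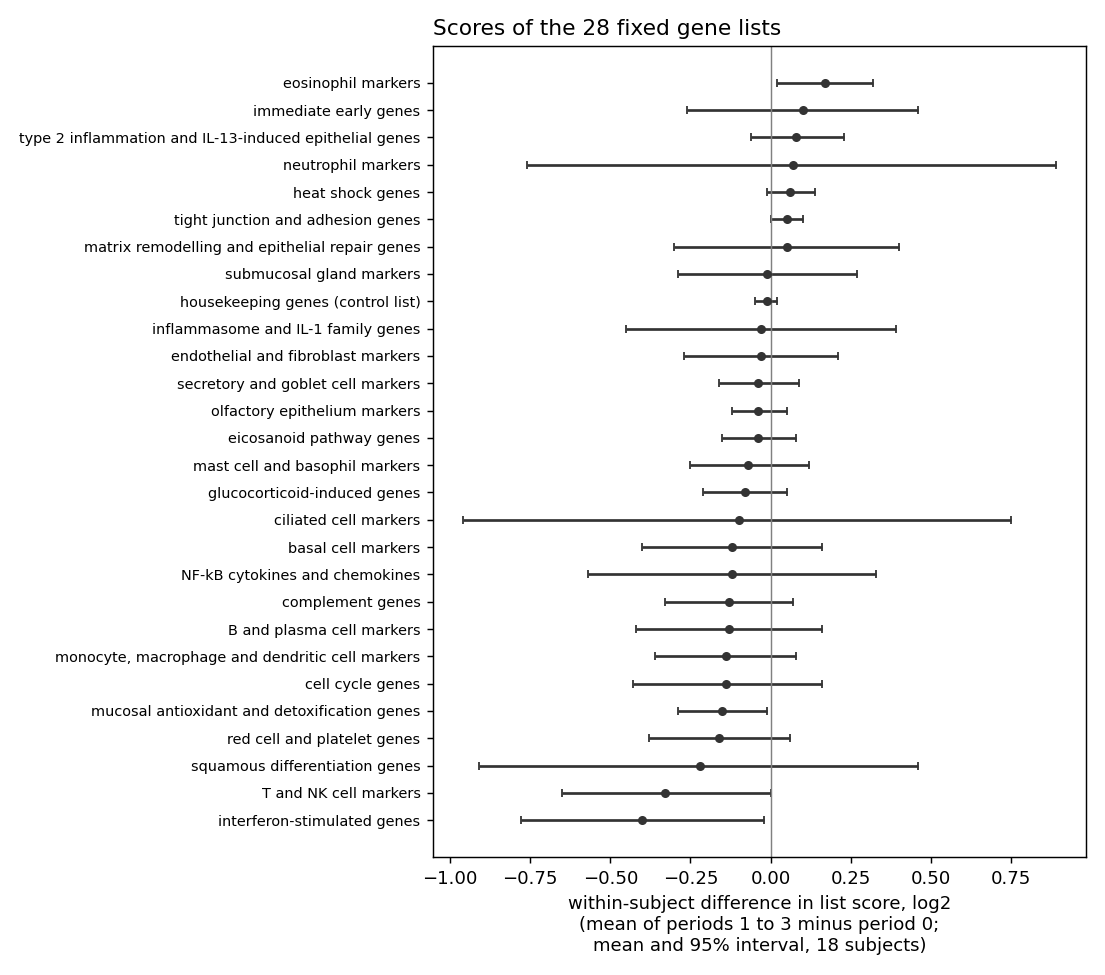
Within-subject difference in the score of each fixed gene list (x axis, log2, mean of periods 1 to 3 minus period 0), with 1 list per line (y axis). Points are means over 18 subjects and bars are 95% intervals, not adjusted for the 28 lists. The interferon list lies lowest at -0.40 and the eosinophil list highest at 0.17, and the widest bars are those of ciliated and neutrophil markers.

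Each challenge period was also set against period 0 alone. In period 1, 36 genes passed, 19 higher and 17 lower. CIART was 4.49-fold lower (-2.17, SE 0.23), NR1D1 2.81-fold lower and PER1 2.18-fold lower. Chosen after their values were seen, HMGCS1 (-0.45, SE 0.081) and DHCR7 (-0.42, SE 0.097), both enzymes of cholesterol synthesis, and the secreted phospholipase PLA2G3 (-1.03, SE 0.23) were lower as well, though the period 1 mean of PLA2G3, 4.72, lay under the 95th percentile of virus probe sets. 6 lists passed with the preset correlation and none with an estimated one: cell cycle genes (median -0.51, 27 of 27 members negative; adjusted p = 0.979 with an estimated correlation), interferon-stimulated genes (-0.33; adjusted p = 0.979), T and NK cells (-0.31; adjusted p = 0.979), ciliated cells (-0.43; adjusted p = 0.991), basal cells (-0.20; adjusted p = 0.979) and, higher, neutrophils (0.72; adjusted p = 0.979). The count for period 1 was 12 without the subject block, 10 in the 15 subjects with all 4 periods, 19 when 1 subject was left out and 126 with 3 list scores as covariates.

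In period 2, 16 genes passed, 6 higher and 10 lower. CIART was 4.17-fold lower, NR1D1 2.73-fold lower and PER1 2.47-fold lower, and INTS13 was 1.26-fold higher (0.33, SE 0.055, adjusted p = 0.000743). Heat shock genes had a median of 0.11 and passed with the preset (adjusted p = 0.000135) and with an estimated correlation (adjusted p = 0.0398), while their paired score differed by 0.09 ± 0.15 (SD, n = 18; permutation p = 0.0306, adjusted p = 0.503). The other 4 lists were lower with the preset correlation alone: squamous differentiation (-0.56; adjusted p = 0.836 with an estimated correlation), interferon-stimulated genes (-0.23; adjusted p = 0.846), antioxidant genes (-0.08; adjusted p = 0.836) and complement (-0.17; adjusted p = 0.836). The count was 7 without the subject block, 85 with array weights and 34 when 1 subject was left out.

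In period 3, 3 genes passed, all lower: NR1D1 (-1.48, SE 0.20, adjusted p = 2.52e-05), CIART (-1.66, SE 0.24, adjusted p = 0.000113) and PER1 (-1.06, SE 0.19, adjusted p = 0.00477). All 30 interferon-stimulated genes had negative differences, with a median of -0.61 (adjusted p = 2.62e-30; adjusted p = 0.127 with an estimated correlation), and 20 of them passed adjusted over the list alone. Among leukocyte lists the median was -0.59 for T and NK cells (adjusted p = 0.173 with an estimated correlation), -0.48 for monocytes, macrophages and dendritic cells (adjusted p = 0.173), -0.35 for neutrophils (adjusted p = 0.561) and -0.18 for B and plasma cells (adjusted p = 0.418), but 0.02 for eosinophils and 0.02 for mast cells and basophils, 2 lists that did not pass. No paired score passed after adjustment: that of the interferon list differed by -0.61 ± 0.94 (SD, n = 15; permutation p = 0.0204, adjusted p = 0.4), that of T and NK cells by -0.51 ± 1.03 (permutation p = 0.0761, adjusted p = 0.493) and that of neutrophils, lower in 8 of 15 subjects, by -0.30 ± 2.05 (permutation p = 0.576, adjusted p = 0.878). In all, 13 lists passed with the preset correlation, 12 lower and 1 higher, and none with an estimated one. The higher list was that of type 2 inflammation, with a median of 0.12 (adjusted p = 0.00365; adjusted p = 0.344 with an estimated correlation). The count was 6 with array weights, 6 with the failed array included and 5 when 1 subject was left out.

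NR1D1, CIART and PER1 passed in all 3 challenge periods, and 9 genes passed in the same direction in both period 1 and period 2. These comparisons share the period 0 arrays. In 20 simulations of unchanged groups no gene passed in both. These simulations draw genes independently, whereas shuffled labels of the real arrays gave up to 4064 calls for period 1. Independent lists would share 0.0144 genes in the same direction, but lists that share period 0 are not independent. Neither value tells whether 9 shared genes are more than chance gives. Over all genes the differences of periods 1 and 2 had a correlation of 0.305 and a covariance of 0.00778. Both were below the mean of 0.517 and 0.0133 in those simulations. When the 18 subjects were divided at random 20 times, so that 9 served for period 1 and the others for period 2, no gene passed in both sets of subjects, and the correlation had a median of 0.011 (-0.532 to 0.448). The number of calls had a median of 0 in either set and was at most 4 for period 1 and 531 for period 2, so these divisions could hardly have shown shared calls.

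The challenge periods were compared with each other because the treatments lie within them. The labels do not give the treatments, and each period may hold arrays of several. These comparisons therefore cannot show whether a treatment had an effect. No gene passed with limma between periods 2 and 1, 3 and 1 or 3 and 2, or in the F test among the 3, where the smallest adjusted p was 0.201, 0.387, 0.619 and 0.325. At an unadjusted p under 0.05 there were 1819, 1179, 989 and 1410 genes, or 9.2%, 5.96%, 5% and 7.13% of those tested. Tests without any difference would give 5%, so the count between periods 3 and 2 is no more than that. Lists passed with the preset correlation in numbers of 6, 15 and 8, and none with an estimated correlation, for which the smallest adjusted p was 0.604, 0.237 and 0.491. Between periods 2 and 1, cell cycle genes had a median of 0.53 and neutrophil markers one of -0.97, with 0.53 for ciliated markers and -0.66 for squamous genes. Between periods 3 and 1, neutrophil markers had a median of -1.16 and type 2 genes one of 0.17. Cell-type and cell cycle lists moved more than the type 2 list there, with 0.48 for cell cycle genes, 0.41 for ciliated markers and -0.45 for monocyte, macrophage and dendritic cell markers. Between periods 3 and 2, interferon-stimulated genes had a median of -0.39. With 3 list scores as covariates 5 genes passed between periods 2 and 1, and leaving out 1 subject gave up to 2 genes between periods 3 and 1 and up to 2 in the F test.

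Whether the glucocorticoid and type 2 responses varied together was asked within subjects over the challenge periods. Over 53 arrays of 19 subjects, the deviations of both list scores from the subject's mean had a Pearson r of -0.11 (permutation p = 0.576, adjusted p = 0.678) and a Spearman rho of 0.068 (permutation p = 0.678, adjusted p = 0.678). Without the 2 arrays farthest from the median glucocorticoid score, r was -0.14 (permutation p = 0.428). Leaving out 1 subject moved r to at most 0.065. The labels give no array batch within which the relation could be recomputed.

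**Figure D3:**
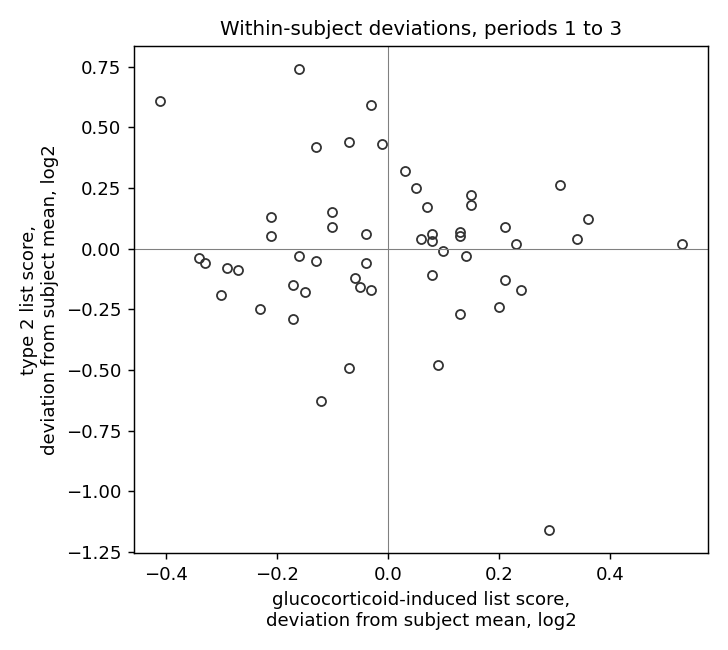
Deviation of each array's glucocorticoid-induced list score (x axis, log2) and type 2 list score (y axis, log2) from its subject's mean over periods 1 to 3. Each circle is 1 of 53 arrays, and no line is drawn because r was -0.11 with a permutation p of 0.576.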

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

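The choice of which differences between challenge periods to give here was made after the results were seen: a list had to pass camera with the preset correlation and have an unadjusted permutation p under 0.05 for its score. None of them passed the permutation test after adjustment over the 28 lists, and none passed camera with an estimated correlation. The score of cell cycle genes was higher in period 2 than in period 1 by 0.50 ± 0.95 (SD, n = 19) and higher in 14 of 19 subjects (permutation p = 0.0214, adjusted p = 0.44). Scores of cell types differed there by as much or more without meeting the rule: 0.50 ± 2.55 for ciliated, -0.86 ± 1.97 for neutrophil and -0.70 ± 1.85 for squamous genes (permutation p = 0.411, 0.07 and 0.116). The score of type 2 inflammation genes was higher in period 3 than in period 1 by 0.38 ± 0.59 (SD, n = 15), in 12 of 15 subjects (permutation p = 0.0258, adjusted p = 0.453). Between the same periods the neutrophil score differed by -1.08 ± 1.80 (SD, n = 15), lower in 11 of 15 subjects (permutation p = 0.0323, adjusted p = 0.453). The interferon score differed by -0.63 ± 1.09 (SD, n = 15) between periods 3 and 2 and was lower in 12 of 15 subjects (permutation p = 0.0271, adjusted p = 0.666). The T and NK score, which did not meet the rule above, moved in the same direction, by -0.55 ± 1.28 (SD, n = 15) and lower in 12 of 15 subjects (permutation p = 0.119, adjusted p = 0.666).

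Signal also appeared in probe sets that the gene tests did not use. With every probe set tested by itself, 14 probe sets without a single gene name passed the threshold for the mean of periods 1 to 3 against period 0, 9 higher and 5 lower. Their log2 differences ran from -0.71 to 0.82.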

How the results depend on the processing

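The covariates of 3 list scores (ciliated, neutrophil and squamous) were chosen after seeing the data; the other settings were planned. For the mean of periods 1 to 3 against period 0 (23 genes), the count became 60 with every probe set tested by itself, 79 with array weights, 57 with the ciliated score as covariate, 48 with 3 scores, and 11 to 32 when each subject in turn was left out. Pairing mattered: without the subject block it was 9, all among the 23, and with a random block for the subject 15, 14 of them among the 23. For period 1 (36 genes) the counts were 95 with every probe set, 12 without the subject block, 68 with array weights, 94 with the ciliated score, 10 in the 15 subjects with all 4 periods, 126 with 3 scores and 19 to 45 with 1 subject left out. For period 2 (16 genes) they were 7 without the subject block, 85 with array weights, 35 with the ciliated score, 26 with 3 scores and 11 to 34 with 1 subject left out. For period 3 (3 genes) they were 6 with array weights, 6 with the failed array included, 5 with 3 scores and 3 to 5 with 1 subject left out. Where no gene had passed, 5 did between periods 2 and 1 with 3 scores, 0 to 2 between periods 3 and 1 and 0 to 2 in the F test with 1 subject left out. The cause of these moves was not tested, beyond the larger number of tests with every probe set and the smaller number of subjects. The other 101 counts and correlations stayed within 1.5 times or kept their side.

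All 23 named genes passed with array weights, with either set of covariates, with trend and robust and with the failed array included; 9 passed without the block, 14 with a random block, 15 in the subjects with all 4 periods, 19 with array medians subtracted, 19 with the mean of a gene's probe sets and 21 after a further quantile normalization. The median difference of all genes was 0.005 as reported, 0.007 after a further quantile normalization and 0.019 with array medians subtracted. Directions reversed only for results that had not passed or whose call rested on the preset correlation. CEACAM6 became 0.01 in the subjects with all 4 periods and YWHAZ 0.01 with the mean of probe sets. List values under these settings are means over the members, unlike the medians given above. With the dimmer genes left out, type 2 genes stood at 0.05, lower than other genes by camera, eosinophil markers at -0.09 and olfactory markers at 0.06. Array weights gave 0.12 for neutrophil markers and 0.02 for gland markers. Between periods 3 and 1, lists that had been called lower changed camera's direction with 3 scores. The NF-kB list stood at 0.22 and then passed camera as higher (adjusted p = 0.0102). The inflammasome list stood at 0.08 (adjusted p = 0.194) and the repair list at -0.02 (adjusted p = 0.623), where the mean stayed negative. Leaving out 1 subject gave paired scores of -0.09 to 0.28 for neutrophils, -0.35 to 0.03 for ciliated cells, -0.11 to 0.03 for glands, -0.06 to 0.04 for endothelium, -0.11 to 0.08 for the inflammasome list and -0.03 to 0.13 for the repair list, and correlations of glucocorticoid and type 2 scores of -0.15 to 0.065. The 81 list tests followed over the settings include all 28 lists of the main comparison, of which only 11 had a call to lose. Of the 81, 63 lost their call under at least 1 setting, the estimated correlation included, and 3 gained one. With the estimated correlation, only heat shock genes in period 2 kept their call. The RNA quality covariate was not run, because the 3' and 5' control probe sets it needs were not among the probe sets used here, and leaving out dim genes gave no value for lists it emptied. Dim transcripts such as IL5 and IL13 lay near the background, which limits what can be said of them.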

Other observations

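The test of the glucocorticoid list without PER1 and KLF9, the choice of clock genes followed and the ranking of shuffled splits along principal components were made after the result was seen; the tests of clock genes outside the called ones, of cell composition, of the interferon lists and of shuffled labels were set out before their results were seen, but the 3 covariates of the test of cell composition were chosen after seeing the data.

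Clock genes that had not passed the threshold had differences of both signs. Of the genes that peak with the lower ones, PER3 was 0.673 times (adjusted p = 0.127) and DBP 0.681 times (adjusted p = 0.128) the level of period 0, while HLF, BHLHE41 and PER2 were 0.783, 0.917 and 0.95 times that level (adjusted p = 0.768, 0.998 and 0.942). Of those that peak in the opposite phase, BMAL1 was 1.21 times (adjusted p = 0.516), NFIL3 1.19 times, CRY1 1.15 times and CLOCK 1.07 times that level (adjusted p = 0.867, 0.729 and 0.901), while NPAS2 had a log2 difference of 0.00 (SE 0.088).

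The lead of clock genes among the lower genes may come from scrapes of the challenge periods having been taken at another time of day than those of period 0, a hypothesis that the labels cannot settle. It needs 5 genes of the opposite phase (BMAL1, NPAS2, CLOCK, CRY1 and NFIL3) to rise against 5 of a like phase (PER2, PER3, DBP, HLF and BHLHE41). The contrast was 0.51 ± 0.84 (SD, n = 18, 95% interval 0.09 to 0.93), above 0 in 15 of 18 subjects (permutation p = 0.0216). For periods 1, 2 and 3 it was 0.57, 0.57 and 0.38 (permutation test, adjusted p = 0.0274, 0.0274 and 0.199). Any other cause that moves clock genes together by phase would give such a contrast, so it cannot single out the time of day. Lower glucocorticoid exposure would also lower other glucocorticoid-induced genes, but the mean difference of the other 30 was -0.03 (95% interval -0.16 to 0.11). They did not fall as a set. The challenge periods pool treatments, however, and whether these 30 genes respond in nasal scrapes was not tested, so their mean cannot settle this explanation. With ciliated, neutrophil and squamous scores as covariates 6 of 6 clock genes still passed, CIART at -1.96 (SE 0.19). These 3 scores differed little on average (-0.10, 0.07 and -0.22), so adding them could hardly move the differences of the clock genes. The fit shows only that these 3 scores do not carry those differences. The T and NK score, which differed by -0.33, was not a covariate, and a change in other cells was not tested. The challenge itself or the corticosteroid doses of the trial acting on clock genes, and array batches, stay open and untested. The labels give neither the treatments nor the batches.

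Interferon-stimulated genes and T and NK cell markers, lists that share 0 genes, had lower scores in the challenge periods, though neither passed after adjustment. A candidate explanation is a smaller share of T and NK cells in those scrapes: over 18 subjects the interferon difference followed the T and NK difference with a slope of 0.79 (95% interval 0.33 to 1.25), and the intercept was -0.14 (95% interval -0.47 to 0.18). The same values would arise if interferon signalling and lymphocyte numbers changed together. The interval of the intercept holds 0 but also the whole difference of -0.40, so the fit cannot settle the explanation. Which cells of the scrapes express the interferon genes was not tested. A single subject with high interferon genes at period 0 does not make up the whole difference: the mean was -0.40 in all and at most -0.31 whichever subject was left out. Such a subject could still account for part of it.

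Shuffling the period labels within subjects gave, with the real labels, 100 splits. For the mean of periods 1 to 3 against period 0, 2 of the 100 splits, the real one among them, gave at least the real 23 genes. The other gave 2374. Shuffled labels thus seldom gave as many genes, but chance is not excluded, and the share was not adjusted over the comparisons. Period 1 gave 36 genes, reached in 2 of 100 splits with a highest other of 4064; period 2 gave 16, reached in 1 split with a highest other of 7; and period 3 gave 3, reached in 1 split with a highest other of 1. Splits that call many times the real number of genes point to a structure of the samples. The splits with 2374, 4064 and 1393 genes also had, in their comparisons, the largest difference along the first principal component of the 99 shuffled splits (t of 3.76, 4.16 and 3.38 in size), and the split with 152 had it along the second (3.17). The first 2 principal components, with 38.7% and 10.3% of the variance, correlated with the ciliated and neutrophil scores at 0.95 and 0.75 in size over 71 arrays. Among the challenge periods the real count was 0, which all 100 splits reach whatever the data, so the splits test nothing in those 4 tests; the highest other split gave 152 between periods 2 and 1, 19 between periods 3 and 1, 1393 between periods 3 and 2 and 19 in the F test.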
